A study of Mus musculus with 17 samples.

How the data were processed

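RNA of colon macrophage preparations was measured in 17 libraries from C57BL/6 mice of 8 weeks, and the labels give 1 mouse number per library. The p of single genes and of permutations measure the spread between these samples. List tests at a preset correlation and Fisher's exact tests compare genes with genes, so their p do not measure that spread. Wild-type mice and mice deficient in MCJ were sampled in 3 conditions named in the library titles: NN (no treatment named; 3 wild-type and 2 MCJ-deficient libraries), NP (DSS for 6 days; 3 and 3) and PP (antibiotic for 7 days, then DSS for 6 days; 3 and 3). Per the labels' protocols, colon tissue was digested with collagenase IV between washing steps, RNA was extracted with Trizol, and libraries were made with the NuGEN Universal Plus mRNA-Seq kit. The labels' protocols name no sorting step for the cells.

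The authors deposited 3 tables of raw counts, 1 per condition, each with 27179 genes under NCBI gene numbers. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2, reads were checked with FastQC and trimmed with Trim Galore, aligned to mm10 with STAR 2.5.4 and analysed with DESeq2. The counting program, the annotation and the strand setting were not given in the labels or the deposited files. The deposited values were whole numbers without an upper limit, as raw counts are. Symbols and GRCm38 coordinates were joined to the gene numbers from RefSeq (25262 genes) and GENCODE M21 (31 genes), and 1886 gene numbers stayed unnamed. These unnamed gene numbers took between 1.39 and 7.32% of the counts of a library.

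Genes with low counts were removed with filterByExpr, libraries were scaled with TMM factors, and the MCJ effect was fitted within each table with the edgeR 4.0.16 quasi-likelihood test. The effects of DSS and of antibiotic before DSS within each genotype, and the differences of the MCJ effect between conditions, came from 1 fit of all 17 libraries. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Lists of genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with the correlation estimated from the data as a second setting, and with fry. R was version 4.3.3. Of the 721 list members, 720 had a gene number in the tables. The test for lists adjusted over the lists tested in that comparison.

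The lists were those of complex I subunits, complex II to V subunits, mitochondrially encoded genes, glycolysis and hypoxia, fatty acid oxidation, oxidative stress and NADPH oxidase, inflammatory cytokines, chemokines, the TNF and NF-kB pathway, Toll-like and NOD receptors, the inflammasome, interferon-stimulated genes, MHC class II presentation, classical activation, alternative activation, phagocytosis with Fc receptors and complement, the lysosome, the cell cycle, extracellular matrix and proteases, endoplasmic reticulum and heat stress, immediate early genes, and mucosal antimicrobial and barrier genes. A further 18 lists held markers of macrophages, monocytes, neutrophils, dendritic cells, eosinophils, mast cells, T and NK cells, B cells, plasma cells, colonocytes, goblet and secretory epithelium, crypt stem and progenitor cells, fibroblasts, smooth muscle and pericytes, endothelium, enteric neurons and glia, adipocytes and red blood cells. The permutation tests of marker sums and mitochondrial shares, and the MCJ effect averaged over conditions, were not planned in advance. The list members, the comparisons of groups, the tests of genes and lists, and the rule for naming genes were fixed before the data were examined. By that rule genes were named as follows: Dnajc15; among genes with an adjusted p under 0.05, an informative symbol and a mean of at least 50 normalized counts, the 10 largest increases and the 10 largest decreases; members of each list that passed, from the 3 with the smallest p; the 2 such members of any other list mentioned; and, for differences between conditions, genes from the 10 with the smallest p. Some results that this rule or the tests of explanations call for are not reported here. Near-identical copies (Hba-a1 and Hba-a2, Hbb genes, Ccl21a, Ccl21b and Ccl21d, Plac9a and Plac9b, Cphx genes, Chil3 and Chil4, Mrgpra2a and Mrgpra2b, Try4 and Try5) share reads, and the division of counts among such copies is uncertain.

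Marker sums (CPM of a marker list, scaled to nuclear counts) and shares of mitochondrial transcripts were compared by exact two-sided permutation of the libraries with scipy 1.17.1 in Python 3.11.15, a family of 24 tests with Benjamini-Hochberg adjustment. Log2 ratios of marker sums used a pseudocount of 0.1 CPM. Folds against a group with 0 counts are bounds against a floor of 3 counts over the group, and ratios against a group with 1 to 3 counts carry a 95% counting interval. Intervals and floors cover counting error only. Other fitted log2 fold changes carry the standard error (SE) of the fit.

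Depth ran from 29194744 to 37083344 counts per library, so counting error was small beside the spread between mice for genes with more than 50 counts. On simulated counts with 200 changed genes, the same test recovered 49% of 8-fold changes in a design like that of NN, 87% in NP and 73% in PP, and 4%, 14% and 1% of 2-fold changes. For DSS it recovered 68% of 8-fold changes in wild-type and 64% in MCJ-deficient mice, and for antibiotic 70% and 67%. For differences of the MCJ effect between conditions it recovered between 44 and 47% of 8-fold changes. On simulated data for NP with 100 lists of 30 genes, the raised list was found and 0 unchanged lists were called. In the real NP libraries, splits that mixed the genotypes gave between 1 and 16 called lists. The simulation therefore does not show that list calls in the real data are free of false calls.

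Alternatives planned in advance were adjusted p limits of 0.01 and 0.1, mean counts of at least 10 or 50, no filter on low counts, a fold limit, other scaling factors, DESeq2 1.42.0, other settings of the list test, a replicate term, and leaving out each library in turn. A fit of all 17 libraries for the MCJ effect, a fit without mitochondrial and unnamed genes, and robust estimation were chosen after the data were seen. No library was left out of the comparisons. Genes below the filter on low counts were left out of the tests, and the alternative with no filter tested them.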

Results

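RNA of macrophage preparations from the mouse colon was sequenced in wild-type mice and in mice deficient in MCJ. This protein, which the gene Dnajc15 encodes, lies in the inner mitochondrial membrane, binds complex I and slows respiration. The 17 libraries covered 3 conditions. NN had no treatment named (3 wild-type, 2 MCJ-deficient libraries), NP had 6 days of DSS, a polymer that injures the colon epithelium (3 and 3), and PP had 7 days of antibiotic before the 6 days of DSS (3 and 3). Depth was 29194744 to 33930200 counts per library in NN, 32505339 to 37083344 in NP and 30645828 to 36461771 in PP. The comparisons ask what loss of MCJ changed in each condition, what DSS changed in each genotype, and what antibiotic before DSS changed.

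The preparations held far more transcripts of the colon epithelium than of macrophages in NN, and the balance moved with treatment. Colonocyte markers, such as the keratin Krt8 and the carbonic anhydrase Car1, summed to 75670 ± 2784 CPM of nuclear counts in wild-type NN and 62020 ± 11570 in MCJ-deficient NN (mean ± SD). Macrophage markers, such as Adgre1 (the surface receptor F4/80) and Csf1r (the receptor of the macrophage growth factor), summed to 71.1 ± 30.8 and 87.9 ± 4.75 CPM. In NP colonocyte markers summed to 60180 ± 12310 CPM in wild-type and 56100 ± 1490 in MCJ-deficient mice, and macrophage markers to 420 ± 99.9 and 2308 ± 1377. In PP colonocyte markers stood at 33740 ± 12110 and 29620 ± 6625 CPM and macrophage markers at 8518 ± 5830 and 7090 ± 1505. The wild-type PP libraries differed among themselves, with macrophage sums of 10629.1, 1925.8 and 12998.5 CPM in replicates 10, 11 and 12. Between genotypes the macrophage sum differed by a log2 ratio of 2.32 in NP without overlap of the libraries (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 allows; adjusted p = 0.48 over 24 tests). The log2 ratio was 0.39 in NN and 0.12 in PP. The permutation tests, and the marker lists put into them, were not among those fixed in advance. The sum of monocyte markers, in NN and NP mostly Plac8, did not follow this course: it was 2499 and 1309 CPM in wild-type and MCJ-deficient NN, 2414 and 1613 in NP, and 1958 and 2375 in PP.

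**Figure D1:**
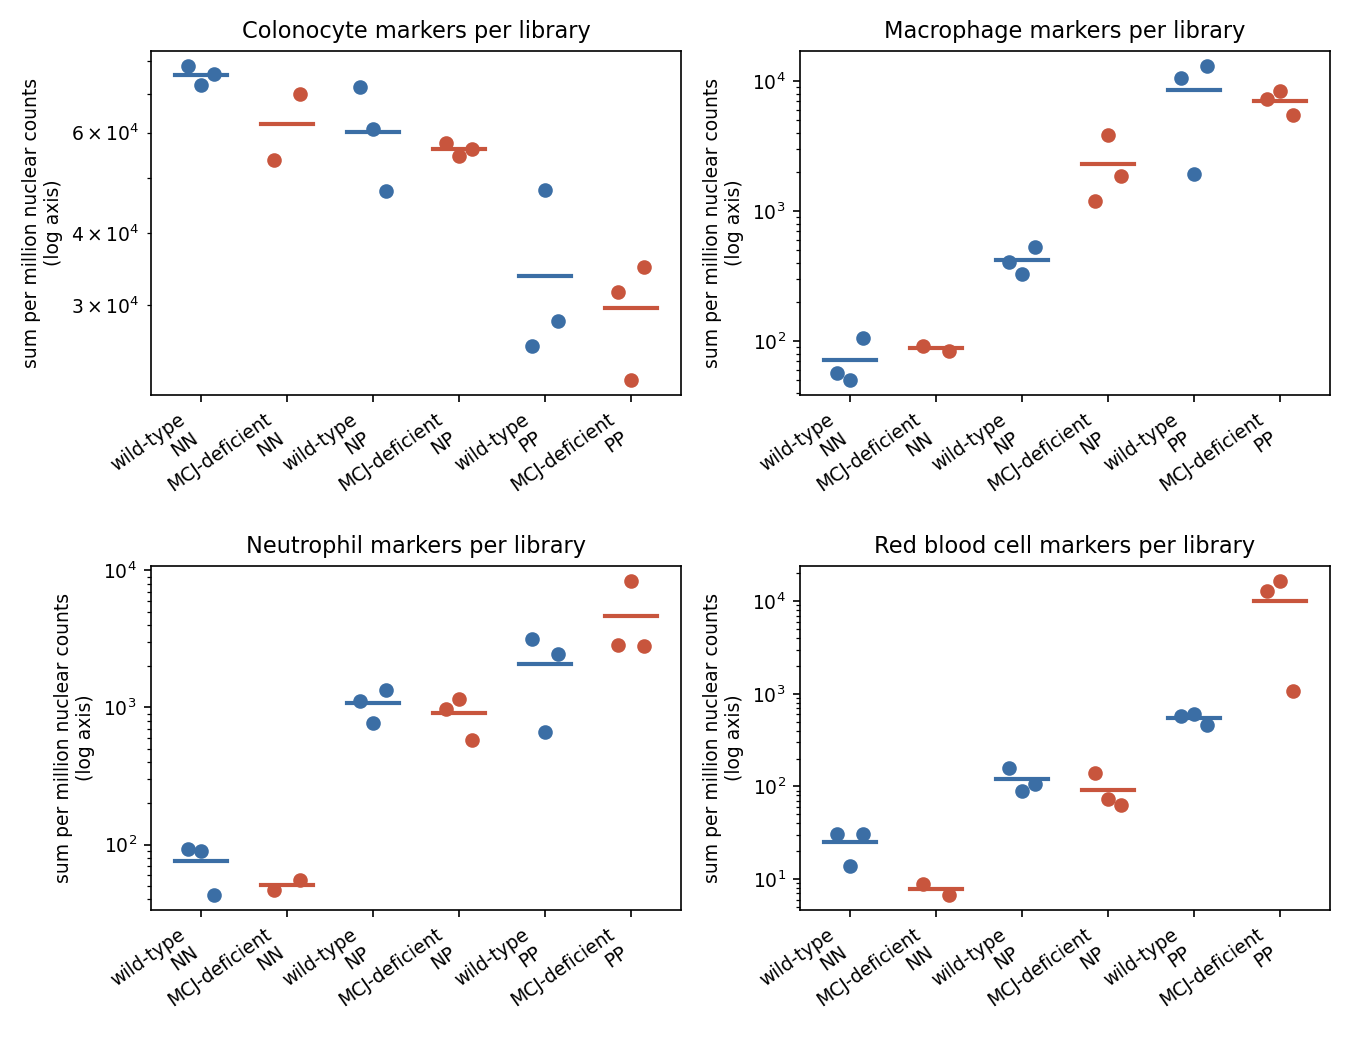
Sums of 4 marker lists per library (points; CPM of nuclear counts on a log axis) in wild-type (blue) and MCJ-deficient (red) mice by condition, with lines at the group means. Macrophage sums in MCJ-deficient NP libraries (1201 to 3850) lay above those of wild-type NP libraries (327 to 526), and red blood cell sums in MCJ-deficient PP libraries (1078 to 16410) above those of wild-type PP libraries (466 to 609).

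The transcript of the deleted gene itself was low in each MCJ-deficient library. Dnajc15 (NCBI gene 66148, chromosome 14, 77826217 to 77874917 on GRCm38) had 359 to 1286 counts in wild-type NN libraries and 104 and 111 in MCJ-deficient ones. It had 1217 to 1534 against 60 to 121 counts in NP, and 817 to 939 against 21 to 105 in PP. It fell in NP (log2 fold change -4.19, SE 0.28; adjusted p = 9.96e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The values in NN (-3.76, SE 0.55) and PP (-4.15, SE 0.76) did not pass in their own tables, with adjusted p of 0.326 and 0.791 by that test (edgeR, Benjamini-Hochberg). Averaged over the 3 conditions in the fit of all 17 libraries, Dnajc15 was the 1 gene of 16958 that passed, at -4.02 (SE 0.38; adjusted p = 7.11e-05, edgeR quasi-likelihood test, Benjamini-Hochberg). In that average 2324 genes had an unadjusted p under 0.05 where 848 would by chance.

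Transcripts of the mitochondrial chromosome, which encodes subunits of the respiratory chain, took a large and variable part of each library. They made up 43.8 ± 5.93% of the counts in wild-type NN and 25.7 ± 3.7% in MCJ-deficient NN (mean ± SD), 37.7 ± 4.76% and 42.2 ± 7.71% in NP, and 43.6 ± 4.84% and 29.3 ± 5.17% in PP. The libraries of the genotypes did not overlap in NN and PP and did in NP. The difference was -18.07 percentage points in NN (exact two-sided permutation test, p = 0.2, the smallest possible there; adjusted p = 0.48 over 24 tests). It was 4.5 in NP (exact permutation, p = 0.4, adjusted 0.686) and -14.34 in PP (exact permutation, p = 0.1, the smallest possible; adjusted 0.48). Permuting genotype within conditions over all libraries gave a mean difference of -9.3 points (exact two-sided permutation, 137 of 4000 arrangements, p = 0.0343). The difference in NP exceeded the mean of those in NN and PP by 20.7 points (exact permutation, 26 of 4000, unadjusted p = 0.0065). Both of these contrasts were chosen after the values had been seen.

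**Figure D2:**
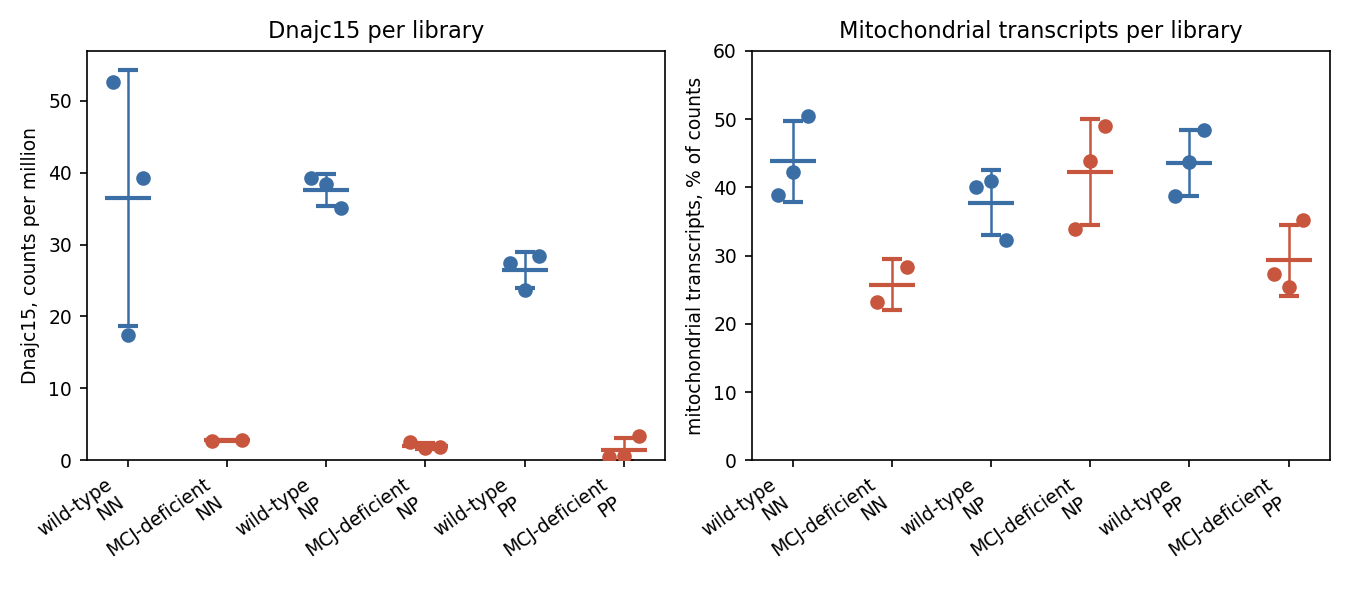
Dnajc15 (left, CPM) and the share of counts from the mitochondrial chromosome (right, percent) per library (points), with the mean and SD of wild-type (blue) and MCJ-deficient (red) groups in NN, NP and PP. The mitochondrial share was 23.12 and 28.35% in MCJ-deficient NN against 38.86 to 50.37% in wild-type NN, and overlapped between genotypes in NP.

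Under DSS without antibiotic, MCJ-deficient preparations held more transcripts of macrophage genes. Receptors that bring white cells into tissue rose: Ccr2, which draws monocytes from the blood (log2 fold change 4.25, SE 0.59), and Ccr3 of eosinophils (4.14, SE 0.72). Itga4, an integrin that binds the vessel wall, rose by 4.27 (SE 0.65). Adgre1 (3.83, SE 0.57), the lysozyme Lyz2 (3.31, SE 0.42) and Csf1r (3.38, SE 0.54) rose as well. So did the scavenger receptor Msr1 (3.69, SE 0.52) and the inhibitory Fc receptor Fcgr2b (2.73, SE 0.35). The lipoxygenase Alox15 (4.53, SE 0.72) and the chitinase-like genes Chil3 (4.01, SE 0.61) and Chil4 (4.83, SE 0.67), typical of alternatively activated macrophages, were higher. Ifnb1, which encodes interferon beta, rose by 5.19 (SE 1.06) and the receptor gene Klra2 by 4.22 (SE 0.88). Ccl20, an epithelial chemokine that draws dendritic and B cells, fell by 2.45 (SE 0.47), and Cd177, a neutrophil surface protein also made by colon epithelium, fell by 1.29 (SE 0.25). Adjusted p of these genes lay between 0.00396 and 0.0485 (edgeR quasi-likelihood test, Benjamini-Hochberg).

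Inflammatory products rose too in MCJ-deficient NP. The cytokine genes Il1a (3.31, SE 0.36), Il1b (2.07, SE 0.27) and Il10 (3.14, SE 0.46) and the prostaglandin synthase Ptgs2 (2.84, SE 0.32) were higher. The chemokines Ccl3 (2.15, SE 0.33), Ccl9 (1.93, SE 0.31) and Cxcl2 (1.81, SE 0.34), and Ncf1 (2.18, SE 0.33) and Ncf4 (2.42, SE 0.38) of the NADPH oxidase, rose with them. The collagenase Mmp13 (3.06, SE 0.37), the matrix protein Spp1 (3, SE 0.38), the transglutaminase Tgm2 (2.03, SE 0.32) and the adhesion molecule Cd44 (2.28, SE 0.28) were higher. So were the versican gene Vcan (2.53, SE 0.37) and S100a4, a calcium-binding protein of monocytes (1.95, SE 0.39). The Fc receptor chain Fcer1g (2.53, SE 0.38) and the lysosomal genes Cd68 (2.87, SE 0.47) and Lgmn (1.87, SE 0.37) completed the group. Adjusted p ranged from 0.00275 to 0.0419 (edgeR quasi-likelihood test, Benjamini-Hochberg). Il1b stood at 84.3 ± 17.3 CPM in wild-type and 354 ± 105 in MCJ-deficient NP, against 1.67 ± 1.15 and 1.58 ± 0.526 in NN.

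**Figure D3:**
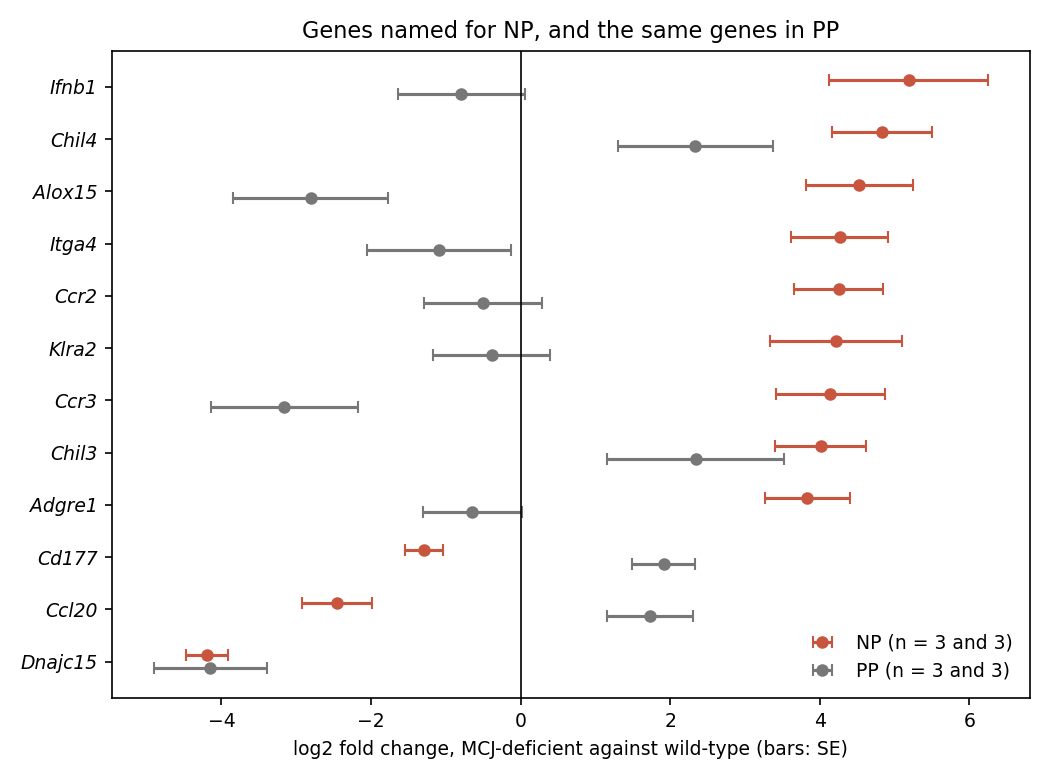
Log2 fold change of MCJ-deficient against wild-type mice (horizontal axis; points with SE bars) for 12 named genes in NP (red) and PP (grey), 3 libraries per genotype in each. In NP Ccr2 stood at 4.25 and Dnajc15 at -4.19, and in PP Dnajc15 stood at -4.15.

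In NP, 142 of 14452 genes were higher and 3 lower in MCJ-deficient mice (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 3 against 3). In the fit of all 17 libraries, chosen after the data had been seen, 0 genes were higher and 1 was lower in NP. An unadjusted p under 0.05 was reached by 1335 genes where 723 would by chance, and the median log2 fold change of the higher genes was 2.56. The number of called genes rested on single libraries. It was 35 without wild-type replicate 7, 20 without wild-type replicate 8, 37 without MCJ-deficient replicate 20 and 72 without MCJ-deficient replicate 21. Of the 35 genes named by rule, 5 (Dnajc15, Il1a, Il1b, Mmp13 and Cd44) passed whichever single library was left out. Calls ended for 23, 28 and 7 without wild-type replicates 7, 8 and 9 (highest adjusted p 0.191, 0.238 and 0.0762, edgeR quasi-likelihood test, Benjamini-Hochberg). They ended for 1, 18 and 11 without MCJ-deficient replicates 19, 20 and 21 (0.105, 0.607 and 0.173).

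As a group, macrophage markers were higher in NP: each of the 14 measured was positive and 9 rose (median 3.2). This list call and the others of NP did not hold with an estimated correlation (adjusted p = 0.447 to 0.657, camera). Of these 14 markers 7 stand in another list as well. Monocyte markers (4 of 8 rose, median 2.12), genes of phagocytosis (11 of 26, 2.11), alternative activation (5 of 18, 2.02) and classical activation (2 of 16, 1.46) moved the same way. So did the inflammatory cytokines (5 of 23, median 1), the TNF pathway (1 of 28, 0.45), the lysosome (2 of 29, 0.33) and the chemokines (of 26, 3 rose and 1 fell, 0.5). Eosinophil markers (1 of 4 rose, median 3.88) and plasma cell markers (0 of 7 called, median 1.82) were higher too. Adjusted over the list alone, 12 macrophage markers, 16 phagocytosis genes, 9 of classical and 6 of alternative activation, 6 cytokines, 4 TNF pathway genes, 3 lysosomal genes, 3 eosinophil and 4 plasma cell markers were higher. Adjusted over the list alone, monocyte markers gave 6 higher and 1 lower, and chemokines 5 and 1. Traf1, an adaptor of TNF receptors (1.36, SE 0.29), was not called. Nor were the eosinophil genes Prg2 (ratio 123, counting interval 21.6 to 4880) and Siglecf (3.62, SE 1.22) and the antibody genes Igkc (4.62, SE 1.03), Jchain (4.13, SE 0.95) and Igha (4.09, SE 0.98).

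Respiratory chain genes encoded in the nucleus were slightly lower in MCJ-deficient NP mice, with none called. Of 37 complex I subunits 36 were negative (median -0.4; Ndufc1 -0.76, Ndufa5 -0.59, Ndufb6 -0.62). Of 38 subunits of complexes II to V 33 were negative (median -0.41; Atp5j2 -0.63, Atp5j -0.63 and, higher, Atp5d 0.78). Genes of endoplasmic reticulum and heat stress were lower as a group (0 of 22 called, 4 adjusted over the list alone, median -0.15), led by the chaperones Hsph1 (-1.31), Hspa8 (-0.91) and Hspa1b (-1.49). Camera passed 14 of 39 lists in NP, with adjusted p from 5.74e-11 (macrophage markers) to 0.0139 (plasma cell markers). Of these 14 lists, 12 passed whichever single library was left out. Chemokines ended without wild-type replicate 8 (0.22) and MCJ-deficient replicate 20 (0.27), and plasma cell markers without wild-type replicate 8 (0.0848; camera, adjusted p). Neutrophil markers (11 measured, median 0.16; Trem1 1.33, Retnlg 1.17) did not pass (adjusted p = 0.46, camera).

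Without treatment, MCJ-deficient preparations held fewer transcripts of the respiratory chain, from both genomes, as groups of genes. None of the list calls in NN held with an estimated correlation (adjusted p = 0.504 to 0.604, camera). The libraries also differed by genotype in how many genes they covered: 12383, 10075 and 13000 genes had 10 or more counts in wild-type NN against 13567 and 13571 in MCJ-deficient NN, and TMM factors were 0.753 to 0.899 against 1.31 to 1.381. Each of the 13 mitochondrially encoded genes was lower (median -1.43, 10 adjusted over the list alone), led by the complex I subunits mt-Nd3 (-1.75, SE 0.35), mt-Nd2 (-1.22, SE 0.34) and mt-Nd1 (-1.53, SE 0.45). Nuclear complex I subunits (35 of 37 negative, median -0.62; Ndufa1 -0.89, Ndufb4 -0.84, Ndufa4 -0.75) and subunits of complexes II to V (33 of 38 negative, median -0.65; Atp5e -0.93, Atp5g1 -0.89, Cox7a2 -0.74) were lower as well. Lists of colonocyte, goblet cell and mucosal genes moved down with them, while crypt stem and progenitor markers had a median of 0.26. Colonocyte markers (13 of 18 negative, 3 down adjusted over the list alone, median -0.32) included the gut hormone Guca2a (-1.23), Car4 (-1.34) and Phgr1 (-1.19). Goblet cell markers (10 of 12 negative, median -0.75) included the mucin Muc2 (-0.78), Tff3 (-1.66) and Clca1 (-1.12). Among genes that defend the mucosa (22 measured, 3 up and 7 down adjusted over the list alone, median -0.31), the antimicrobial ribonuclease Ang4 had a value of -3.51 (SE 0.4). The goblet cell product Retnlb had -3.3 (SE 0.63) and the lectin Reg4 1.24 (SE 0.33). Ang4 stood at 142 ± 17.7 CPM in wild-type and 13 ± 7.46 in MCJ-deficient NN.

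Markers of fibroblasts, endothelium and red blood cells were lower too in MCJ-deficient NN, as groups of genes. Each of 9 fibroblast markers (median -3.35; the matrix genes Dcn -3.35, Dpt -3.74, Lum -4.66), each of 10 endothelial markers (median -1.86; Tek -4.89, Lyve1 -1.29, Plvap -2.3) and each of 3 red blood cell markers (median -1.91; Hba-a2 -1.91) was negative. Fibroblast sums were 18, 65 and 331.5 CPM in wild-type NN replicates 1, 2 and 3 against 16.3 and 12, so the gap was largest for replicate 3. Endothelial sums overlapped between genotypes (36.1, 14.7 and 72 against 13.2 and 19.5). Smooth muscle markers had a median of -0.32, and their sums overlapped too. Chemokines (15 of 20 negative, median -0.7; Ccl9 -1.84, Ccl6 -0.68, Cxcl9 -5.16) were lower as well. The list of stress genes passed toward lower values through a few heat shock genes (Hspa1b -1.25, Hspa1a -1.22, Hspb1 -2.52), with 12 of 22 negative and a median of -0.06. Camera passed 11 of 34 lists in NN, with adjusted p from 5.27e-14 to 0.0488. No single gene passed (0 of 13559 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 3 wild-type against 2 MCJ-deficient libraries). An unadjusted p under 0.05 was reached by 1124 genes where 678 would by chance, and DESeq2 called 312 (21 higher, 291 lower). Without MCJ-deficient replicate 14 edgeR called 1 gene.

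In NN, 6 of the 11 lists passed whichever single library was left out. The call of chemokines ended without wild-type replicate 2 (adjusted p = 0.0537, camera). That of stress genes ended without wild-type replicates 1 (0.168) and 2 (0.123) and MCJ-deficient replicate 14 (0.408). Mucosal genes ended without wild-type replicate 1 (0.0585) and MCJ-deficient replicate 13 (0.0765), and colonocyte markers without MCJ-deficient replicate 13 (0.119). Endothelial markers ended without wild-type replicate 3 (0.145) and MCJ-deficient replicate 13 (0.0876). The NN libraries also differed in sex-linked transcripts: Xist, from the inactive X chromosome, had 2048, 1100 and 1 counts in wild-type replicates 1, 2 and 3 and 7176 and 7950 in the MCJ-deficient ones.

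After antibiotic and DSS, transcripts of red blood cells and neutrophils stood higher, and those of muscle and proliferation lower, in MCJ-deficient preparations, as groups of genes. None of the list calls in PP held with an estimated correlation (adjusted p = 0.872 to 0.961, camera). Red blood cell markers (4 of 4 up adjusted over the list alone, median 4.45) included the globins Hbb-bs (4.47, SE 0.8) and Hba-a2 (4.43, SE 0.87) and Alas2, the heme synthesis enzyme of red cell precursors (5.61, SE 1.1). Their sum was 549 ± 74.8 CPM of nuclear counts in wild-type and 10170 ± 8055 in MCJ-deficient PP (13020.7, 16411.8 and 1077.8 in replicates 22, 23 and 24). Neutrophil markers were higher (11 of 12 positive, 4 adjusted over the list alone, median 1.5), led by the granule genes Ngp (5.6) and Ltf (2.5) and the calprotectin gene S100a8 (2.64). Neutrophil sums overlapped between genotypes, at 3154.7, 661 and 2456.3 CPM in wild-type PP against 2872.5, 8308.9 and 2827.2 (exact two-sided permutation, p = 0.3). Each of 22 genes of glycolysis and hypoxia was positive (median 0.83), led by the oxygen sensor Egln3 (1.69), the glucose transporter Slc2a1 (1.54) and pyruvate kinase Pkm (1.66). Adipocyte markers (4 of 4 positive, 2 adjusted over the list alone, median 2.59; Cfd 3.41, Retn 2.74, Adipoq 2.45) were higher too.

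Smooth muscle markers were lower in MCJ-deficient PP (10 of 10 negative, 2 adjusted over the list alone). Their median was -2.42, also with genes at 0 set at their bound (Rgs5 -2.57, Actg2 -2.7, and Synm at least 44.8-fold lower). Smooth muscle sums overlapped between genotypes, at 171.4, 267.3 and 1040 CPM in wild-type replicates 10, 11 and 12 against 97.5, 88.1 and 200.6 (exact two-sided permutation, p = 0.2). Cell cycle genes (28 of 30 negative, median -0.66; Pcna -0.54, Mcm2 -1.04, Mcm4 -0.58) and complex I subunits (35 of 37 negative, median -0.24; Ndufc1 -0.77) were lower as well. Mitochondrially encoded genes (12 of 13 negative, median -0.58; mt-Nd4l -0.86, mt-Nd2 -0.74, mt-Cytb -0.76) moved with them. So did markers of fibroblasts (7 of 10 negative, median -2.12; Lum -3.16, Col1a2 -3.86, Col1a1 -3.24) and of eosinophils (4 of 4 negative, 2 adjusted over the list alone, median -2.75; Ccr3 -3.16, Siglecf -3.19, Il5ra -1.99). Sums of both overlapped between genotypes (exact two-sided permutation, p = 0.6 and 0.4). Fibroblast sums were 159.3, 328.5 and 1549 CPM in wild-type PP against 160.4, 405 and 158.4. Eosinophil sums were 390.8, 15.6 and 133.7 against 19.9, 19.9 and 18.6. Small shifts upward came from the TNF pathway (median 0.34; Ier3 1.39), the cytokines (0.33; Osm 1.93, Csf3 2.09, Lif 1.56) and the lysosome (0.43; Ctsa 0.92, Glb1 0.86). Classical activation (0.61; Nos2 4.72, Cd38 0.66, Acod1 1.26), receptors of microbes (0.14, 1 adjusted over the list alone) and interferon-stimulated genes (0.48; Tap1 1.48, Psmb8 0.97 and, lower, Ifi44 -2.86) followed. The direction of classical activation reversed without wild-type replicate 11 (adjusted p = 0.914, camera) and that of interferon-stimulated genes without MCJ-deficient replicate 23 (0.776).

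Camera passed 16 of 40 lists in PP, with adjusted p from 8.03e-08 (smooth muscle markers) to 0.0416. Whichever single library was left out, 6 of the 16 passed (mitochondrially encoded genes, glycolysis and hypoxia, and markers of neutrophils, smooth muscle, adipocytes and red blood cells). Calls ended for 1, 8 and 2 lists without wild-type replicates 10, 11 and 12 (highest adjusted p 0.226, 0.965 and 0.285, camera). They ended for 4, 7 and 2 without MCJ-deficient replicates 22, 23 and 24 (0.387, 0.776 and 0.0966), and without replicate 23 the number of lists was 10. No single gene passed in PP (0 of 14556 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3 against 3). An unadjusted p under 0.05 was reached by 758 genes where 728 would by chance, and DESeq2 called 88. Without MCJ-deficient replicate 24 edgeR called 6 genes. The lectin Reg4 (-5.63, SE 0.68) and the endotoxin-binding gene Lbp (2.34, SE 0.31) had the smallest adjusted p (0.307 for each, edgeR quasi-likelihood test, Benjamini-Hochberg).

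The effects of MCJ loss were weakly related across conditions. Across genes, which are not independent replicates, log2 fold changes of NN and NP had a Pearson correlation of 0.12, those of NP and PP 0.03 and those of NN and PP 0.05. Spearman correlations were 0.24, 0.13 and 0.11, and 61.3, 55.9 and 55.4% of genes had the same sign. Among genes with a mean count of at least 50 the Pearson correlations were 0.25, 0.07 and 0.1. Of the 142 genes higher in NP, 101 were positive in PP, with a median of 0.38. That median was 0.99, -0.14 and 0.46 without wild-type replicates 10, 11 and 12 and 0.39, 0 and 0.57 without MCJ-deficient replicates 22, 23 and 24. In NN 40 of the 88 that could be measured were positive (median -0.09). Under DSS in wild-type mice 137 of the 142 were positive and 73 rose.

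Tested as differences between conditions, the MCJ effect differed for a few genes, among them some of the epithelium and of red cells. From NN to PP, 4 genes shifted up and 5 down of 16958 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 1400 at an unadjusted p under 0.05, 162 by DESeq2). Sis, the sugar-splitting sucrase of enterocytes (-6.97, SE 0.88), and Reg4 (-6.94, SE 1.01) shifted down. Plet1, a surface protein of epithelial progenitors (3.59, SE 0.5), and the globins Hbb-b1 (6.49, SE 0.97), Hba-a2 (6.28) and Hba-a1 (6.1) shifted up. Bicd1 (-9.38), a dynein adaptor, and Cenpq (-7.85), of the kinetochore, also shifted down. Sis, Bicd1 and Cenpq had 0 or 1 counts per library in wild-type NN, so that the size of their shifts depends on the prior count. Of the 8 named genes Sis passed whichever single library was left out. Calls ended for 7 and 6 without MCJ-deficient NN replicates 13 and 14 (highest adjusted p 0.288 and 0.411, edgeR quasi-likelihood test, Benjamini-Hochberg) and for 4, 3 and 2 without MCJ-deficient PP replicates 22, 23 and 24 (0.141, 0.0897 and 0.0773). They ended for 1 each without wild-type NN replicates 1 and 2 (0.0553 and 0.0528), and for 2, 2 and 4 without wild-type PP replicates 10, 11 and 12 (0.107, 0.0569 and 0.0841). The count of genes was 23, 14 and 78 without wild-type NN replicates 1, 2 and 3, 1 and 2 without MCJ-deficient NN replicates 13 and 14, and 4 without MCJ-deficient PP replicate 22.

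No gene passed for NP against NN (0 of 16958, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 950 at an unadjusted p under 0.05, 141 by DESeq2) or for PP against NP (0; 886 and 81). The first count was 9, 3 and 41 without wild-type NN replicates 1, 2 and 3 and 1 without MCJ-deficient NP replicate 19. The second was 1 without MCJ-deficient NP replicate 19, 1 and 29 without wild-type PP replicates 10 and 11 and 7 without MCJ-deficient PP replicate 24. Ang4 came nearest in both, with a shift of 6.28 (SE 0.95, adjusted p = 0.0621) from NN to NP and -5.63 (SE 0.84, adjusted p = 0.0548) from NP to PP (edgeR quasi-likelihood test, Benjamini-Hochberg). Retnlb (3.95, SE 0.78) and the ferroxidase Cp (5.13, SE 0.98) followed from NN to NP. From NP to PP followed Cd177 (3.18, SE 0.55), Hbb-b1 (5.24, SE 0.83), Ccr3 (-7.32, SE 1.29) and Alox15 (-7.37, SE 1.35).

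As groups, macrophage markers (13 of 14 negative, 10 adjusted over the list alone, median -3.72) and eosinophil markers (4 of 4 negative, median -7.08) had a lower MCJ effect in PP than in NP. With an estimated correlation none of the lists of the 3 differences passed (smallest adjusted p 0.406, 0.173 and 0.176 for NP against NN, PP against NP and PP against NN, camera). The log2 sum of macrophage markers had an MCJ effect lower by 2.2 in PP than in NP, which labels permuted within conditions reached in 46 of 400 arrangements (exact two-sided permutation, p = 0.115). Glycolysis and hypoxia (21 of 22 positive, median 0.73) and red blood cell markers (median 5.01) had a higher one. Mitochondrially encoded genes had a higher effect in NP than in NN (13 of 13 up adjusted over the list alone, median 1.57) and a lower effect in PP than in NP (13 of 13 negative, median -0.66). Camera passed 22, 15 and 20 of 40 lists for NP against NN, PP against NP and PP against NN. Single libraries were not left out of these list tests.

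**Figure D4:**
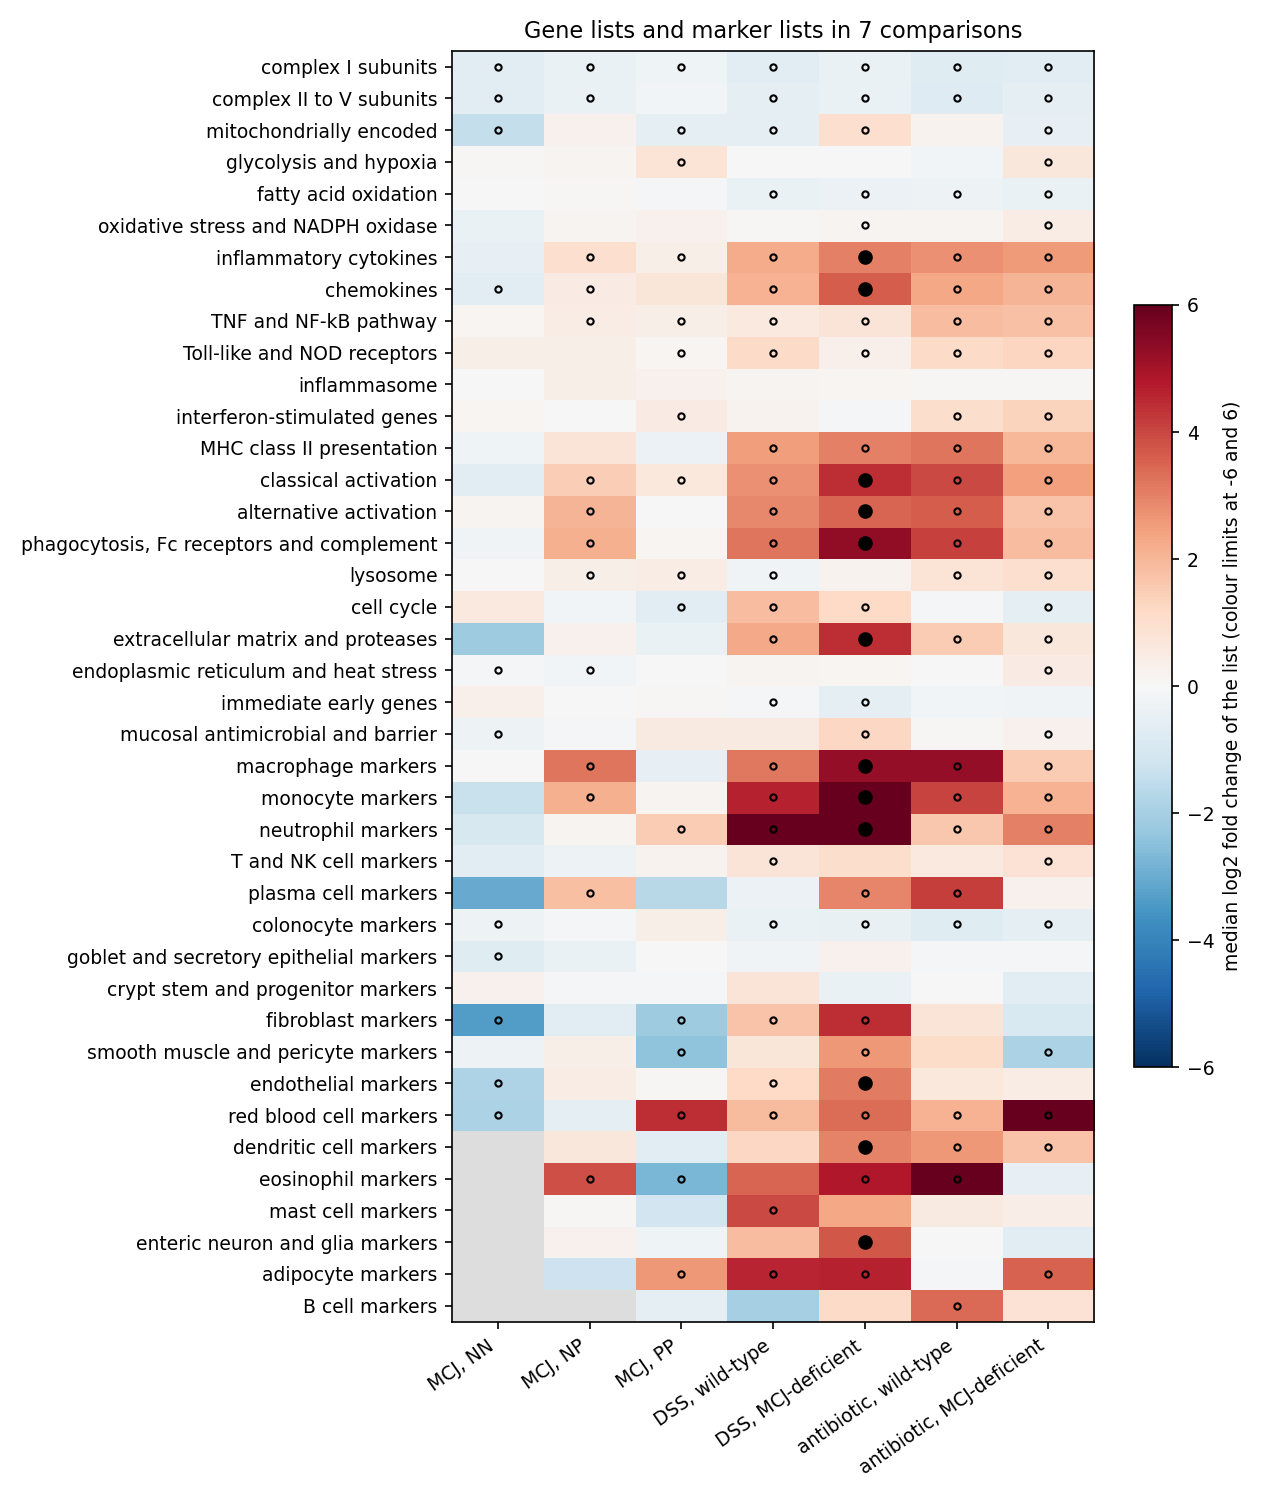
Median log2 fold change (colour, limits -6 to 6) of 40 gene and marker lists in 7 comparisons. Small open dots mark lists with an adjusted p under 0.05 by camera at the preset correlation. Large filled dots mark those that also passed with an estimated correlation, and grey cells were not measured. Large dots appear for DSS in MCJ-deficient mice, where 12 lists passed in both ways.

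DSS without antibiotic raised transcripts of neutrophils and inflammation in the wild-type preparations and lowered a smaller number of genes, some of the epithelium. The calprotectin genes S100a8 (8.29, SE 0.81) and S100a9 (8.79, SE 0.82), which starve microbes of metal, rose. So did the inflammasome sensor Nlrp3 (6.73, SE 0.73), the complement receptor C5ar1 (6.82, SE 0.74) and Acod1, which makes itaconate (6.48, SE 0.74). Il1b (5.64, SE 0.67), the cytokine Osm (5.25, SE 0.79), Il10 (5.35, SE 0.9) and Cxcl2 (5.13, SE 0.74) rose with them. Genes at 0 counts in the untreated wild-type libraries rose at least 135-fold (the protease Adam8), 134-fold (Sgo1, which guards sister chromatids), 104-fold (Cd300lg), 94.8-fold (Spdl1), 94-fold (the mast cell protease Mcpt1) and 90.6-fold (Ncf1). Cenph of the kinetochore rose at least 85.8-fold, Mrgpra2b and Mrgpra2a 79.1- and 76.8-fold and the chitinase-like Chil1 75.9-fold. Wild-type NN libraries covered fewer genes than wild-type NP libraries (10075 to 13000 against 13612 to 14579 genes with 10 or more counts), and untreated MCJ-deficient libraries had counts of some of these genes (Adam8 79 and 14, Cenph 19 and 77). The angiogenins Ang4 (-4.85, SE 0.65) and Ang5 (-5.62, SE 1.35), the lectin Itln1 (-2.9, SE 0.72), Retnlb (-2.42, SE 0.51) and the deiodinase Dio1 (-2.3, SE 0.45) fell. Tppp3 (-3.24, SE 0.43), which binds tubulin, Capsl (-4.27, SE 0.91) and Crip1 (-1.95, SE 0.32) fell too. Adjusted p of these genes with a fitted value lay between 3.8e-05 and 0.0419 (edgeR quasi-likelihood test, Benjamini-Hochberg).

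In wild-type mice under DSS, each of 12 neutrophil markers was positive and 9 rose (median 6.92, 6.15 with genes at 0 at their bound; Csf3r at a ratio of 614, counting interval 110 to 24300). This and the other list calls of this comparison did not hold with an estimated correlation (smallest adjusted p 0.0955, camera). Monocyte markers (6 of 8 rose, median 5.23, 4.62 with bounds; Vcan ratio 87.7, counting interval 24 to 728) and macrophage markers (14 of 14 positive, 6 rose, median 3.18; Lyz2 4.04, C1qc 4.68) were higher. Phagocytosis genes (12 of 26 rose, median 4.07, 3.22 with bounds; Fcgr3 5.51), matrix and protease genes (28 of 28 positive, 6 rose, median 2.27; Mmp13 5.78) and cell cycle genes (30 of 30 positive, 2 rose, median 1.87; Rrm2 3.48, Mcm4 1.9) followed. MHC class II genes (4 of 13 rose, median 2.97, 2.52 with bounds; H2-Ab1 3.24, Cd74 2.97), cytokines (5 of 24, 2.22, 2.21 with bounds), chemokines (6 of 28, 2.1; Ccl4 5.72, Ccl2 5.26) and microbe receptors (4 of 25, 1.19, 1.13 with bounds; Cd14 2.67) were higher too. Adjusted over the list alone, 11 neutrophil, 6 monocyte and 11 macrophage markers, 16 phagocytosis, 13 matrix, 13 cell cycle and 7 MHC class II genes, 7 cytokines, 11 chemokines and 9 microbe receptors rose. Complex I (36 of 37 negative, median -0.62; Ndufa1 fell by 1.07), complexes II to V (35 of 38, -0.53; Atp5e fell by 0.99) and mitochondrially encoded genes (13 of 13, -0.6) were lower. Fatty acid oxidation (median -0.4) and colonocyte markers (2 of 18 fell, 6 adjusted over the list alone, median -0.4; Guca2a fell by 1.75, Phgr1 by 1.62) were lower as well. Other lists of the epithelium did not pass: mucosal antimicrobial and barrier genes (of 24, 3 rose and 3 fell, median 0.55), crypt markers (0.77) and goblet cell markers (-0.19; adjusted p = 0.763, 0.437 and 0.131, camera). Immediate early genes had a median of -0.14 and a mean of 0.36 with a test toward lower values.

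DSS in wild-type mice raised 381 and lowered 33 of 16958 genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3 against 3; 2697 at an unadjusted p under 0.05, 1092 by DESeq2). Without wild-type NN replicate 2 267 were called, and without wild-type NN replicate 3 769. Of 70 named genes 41 passed whichever single library was left out. Calls ended for 22, 22 and 9 without wild-type NN replicates 1, 2 and 3 (highest adjusted p 0.0957, 0.183 and 0.0877, edgeR quasi-likelihood test, Benjamini-Hochberg). They ended for 17, 14 and 14 without wild-type NP replicates 7, 8 and 9 (0.143, 0.241 and 0.101). Camera passed 26 of 40 lists (adjusted p from 1.02e-14 to 0.0426). Of these 26, 18 passed whichever single library was left out. List calls ended for 2, 4 and 6 without wild-type NN replicates 1, 2 and 3 (highest adjusted p 0.495, 0.241 and 0.152, camera) and for 2, 2 and 7 without wild-type NP replicates 7, 8 and 9 (0.17, 0.21 and 0.217). Macrophage marker sums went from 71.1 to 420 CPM of nuclear counts between these groups.

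In MCJ-deficient mice DSS raised transcripts of inflammation, macrophages and neutrophils. Ptgs2 (9.07, SE 1.24), Il10 (8.93, SE 1.16), Osm (8, SE 0.96), Il1b (7.8, SE 0.89) and Acod1 (6.59, SE 0.86) rose. Ccr2 (7.87, SE 1.26), Lyz2 (7.32, SE 1.06), Mmp13 (7.57, SE 1.01), Nlrp3 (6.7, SE 0.77), the complement gene C1qb (6.01, SE 0.97), S100a8 (9.39, SE 1.04) and S100a9 (8.91, SE 1) rose as well. From 0 counts in untreated MCJ-deficient libraries, Ms4a6c of monocytes rose at least 626-fold, the monocyte attractant Ccl2 528-fold, the neutrophil collagenase Mmp8 329-fold and Ifitm6 274-fold. The RNA sensor Tlr13 rose at least 218-fold and Stx11 178-fold. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were at least 942-, 576- and 399-fold higher in the DSS libraries. Both untreated MCJ-deficient libraries had 0 counts of these genes and high Xist, and Xist had 4, 0 and 3822 counts in the MCJ-deficient NP libraries. The groups thus differed in sex-linked transcripts as well as in DSS, and a part of sex in the calls of this comparison was not separated from DSS. The RNAs Rmrp and Rpph1, parts of RNA-cleaving enzymes, fell by 4.94 (SE 1.06) and 4.81 (SE 1.02), and the nuclear RNA Malat1 by 1.7 (SE 0.37). Adjusted p of the genes with a fitted value lay between 0.00026 and 0.0171 (edgeR quasi-likelihood test, Benjamini-Hochberg).

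In this comparison 12 lists passed camera at the preset and at an estimated correlation. They were phagocytosis (19 of 26 rose, median 5.99, 5.3 with genes at 0 at their bound), matrix and proteases (11 of 28, 4.53, 4.41 with bounds), macrophage markers (10 of 14, 5.27), monocyte markers (7 of 8, 7.01) and neutrophil markers (9 of 12, 7.87, 6.47 with bounds). Chemokines (8 of 28, 4.26, 3.64 with bounds), cytokines (8 of 24, 3.78, 3 with bounds), classical activation (6 of 16, 4.59, 4.42 with bounds) and alternative activation (5 of 22, 5.1, 3.51 with bounds) belonged to them. Markers of dendritic cells (1 of 9 rose), endothelium (3 of 10, median 3.14; Lyve1 2.74, Plvap 3.85) and enteric neurons and glia (7 of 7 positive, 0 called) did as well. Adjusted over the list alone, 21 phagocytosis, 19 matrix and 17 chemokine genes, 11 cytokines, 13 and 10 genes of classical and alternative activation, and 12 macrophage, 7 monocyte, 11 neutrophil, 1 dendritic, 6 endothelial and 0 neural markers rose. Their adjusted p lay between 0.0184 and 0.0498 with an estimated correlation (camera). Mitochondrially encoded genes were higher here (13 of 13 positive, 7 adjusted over the list alone, median 1; adjusted p = 6.46e-08, camera, and 0.187 with an estimated correlation). Complex I and complexes II to V of the nucleus were lower (median -0.42 for each; adjusted p = 0.32 and 0.318 with an estimated correlation). Barrier genes were higher (3 of 24 rose, 7 up and 2 down adjusted over the list alone, median 1.24; the iron-binding Lcn2 6.51, Saa3 4.73, Duoxa2 2.41; adjusted p = 0.197 with an estimated correlation, camera).

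DSS in MCJ-deficient mice raised 346 and lowered 6 genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3 against 2; 1402 at an unadjusted p under 0.05, 787 by DESeq2). Without MCJ-deficient NN replicate 13 45 were called, and without replicate 14 110. Of 63 named genes 18 passed whichever single library was left out. Calls ended for 44 and 36 without MCJ-deficient NN replicates 13 and 14 (highest adjusted p 0.449 and 0.417, edgeR quasi-likelihood test, Benjamini-Hochberg). They ended for 6, 13 and 7 without MCJ-deficient NP replicates 19, 20 and 21 (0.0706, 0.119 and 0.0793). Camera passed 30 of 40 lists, and 29 did whichever single library was left out. Colonocyte markers ended without MCJ-deficient NN replicate 14 (adjusted p = 0.128, camera). The genotypes shared 193 of their genes raised by DSS where 7.8 would be shared by chance (Fisher's exact test, p = 2.34e-243; genes are not independent replicates), and 0 of the lowered ones.

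Antibiotic before DSS, against DSS alone, went with more transcripts of macrophages and of antigen presentation in wild-type mice. C1qb (5.8, SE 0.76) and C1qc (5.46, SE 0.79), which opsonise dying cells, Adgre1 (5.83, SE 0.8) and Ccr2 (6.39, SE 0.89) rose. The MHC class II genes H2-Ab1 (3.98, SE 0.57) and H2-Eb1 (4.32), Il10 (5.58, SE 0.77), Il1a (5.77, SE 0.82), Il1b (4.33, SE 0.62), Nlrp3 (3.71, SE 0.51) and the antiviral gene Rsad2 (3.69, SE 0.65) rose with them. Spic, a factor of iron-recycling macrophages, rose at least 293-fold, Cst7 257-fold, H2-M2 204-fold, Gpr18 160-fold and Dcstamp, which fuses macrophages, 88.8-fold. Ocstamp rose with a ratio of 395 (counting interval 109 to 3270), Ear2 of 216 (73.4 to 1050), Rasgrp1 of 1140 (204 to 45100), Abcg3 of 715 (128 to 28300) and the antibody segment Ighv10-1 of 1150 (318 to 9510). Ang4 (4.96, SE 0.66) and Retnlb (3.59, SE 0.54) rose as well. Hoxd13 (-3.68, SE 0.72) and Hoxb13 (-2.97, SE 0.75), which mark the hindmost gut, fell. Fxyd4 (-4.41), Ephb6 (-3.84), Tgm3 (-3.15), Tnni1 (-3.13), Eno3 (-3.03), B3gnt7 (-2.92), Ttr (-2.81) and AI854703 (-2.8) fell too. Adjusted p of the genes with an SE in these sentences lay between 0.00122 and 0.0315 (edgeR, Benjamini-Hochberg).

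As groups, macrophage markers (14 of 14 positive, 11 rose, median 5.27), MHC class II genes (13 of 13, 6 rose, 3.2), phagocytosis (16 of 26 rose, 4.11; Msr1 5.87), classical activation (11 of 16, 3.96; Tgm2 4.37, Ptgs2 4.65) and alternative activation (8 of 22, 3.81, 3.64 with genes at 0 at their bound; Clec7a 4.96) were higher. None of the list calls of this comparison held with an estimated correlation (smallest adjusted p 0.153, camera). The TNF pathway (11 of 28, 1.86; Cd40 5.78, Traf1 2.99), cytokines (10 of 24 rose and 1 fell, 2.75), chemokines (10 of 28, 2.31; Ccl9 4.32, Ccl3 3.84) and the lysosome (10 of 29, 0.84; Cd68 4.9, Lgmn 3.37) followed. Interferon-stimulated genes (3 of 38, 1.05; Isg15 3.09, Oasl1 2.69) and markers of eosinophils (2 of 4, 6.54; Ccr3 6.65) and plasma cells (3 of 8, 4.13; Igkc 7.35) were higher too. Adjusted over the list alone, 13 macrophage markers, 11 MHC class II, 18 phagocytosis, 13 classical and 12 alternative activation genes, 20 TNF pathway genes, 12 cytokines, 17 chemokines, 13 lysosomal and 4 interferon-stimulated genes, and 3 eosinophil and 5 plasma cell markers rose. Complexes II to V (38 of 38 negative, 7 fell, 29 adjusted over the list alone, median -0.76; Cox6c -1.2) and complex I (36 of 37, 1 fell, 26 adjusted over the list alone, -0.75; Ndufs5 -1.17) were lower. Colonocyte markers (4 of 18 fell, 12 adjusted over the list alone, -0.74) were lower as well, with the water channel Aqp8 (-2.31), Car4 (-1.77) and Lypd8 (-1.71). Camera passed 23 of 40 lists (adjusted p from 1.32e-16 to 0.028). Of these, 17 passed whichever single library was left out. List calls ended for 1, 2 and 2 without wild-type NP replicates 7, 8 and 9 (highest adjusted p 0.0578, 0.107 and 0.0568, camera) and for 3, 1 and 3 without wild-type PP replicates 10, 11 and 12 (0.176, 0.0955 and 0.106).

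Wild-type mice had 591 genes higher and 157 lower with antibiotic (edgeR, Benjamini-Hochberg, 3 against 3, unadjusted p under 0.05 for 2822, 1380 by DESeq2). The number was 225, 310 and 321 without wild-type NP replicates 7, 8 and 9 and 215, 1313 and 311 without wild-type PP replicates 10, 11 and 12. Of 81 named genes 39 passed whichever single library was left out. Calls ended for 38, 29 and 26 without wild-type NP replicates 7, 8 and 9 (highest adjusted p 0.238, 0.189 and 0.184, edgeR, Benjamini-Hochberg). They ended for 39, 3 and 29 without wild-type PP replicates 10, 11 and 12 (0.282, 0.0898 and 0.176). Macrophage marker sums went from 420 to 8518 CPM of nuclear counts and colonocyte sums from 60180 to 33740 between these groups.

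In MCJ-deficient mice antibiotic before DSS raised red blood cell transcripts, with inflammatory and antiviral genes. Hba-a2 (7.12, SE 0.75), Hba-a1 (7.09, SE 0.77) and Hbb-bs (7.13, SE 0.95) rose. Nos2, which makes nitric oxide (6.13, SE 1.23), Ccl5 (6.1, SE 1.09), the acute phase gene Saa3 (5.14, SE 0.94), Hmox1, which degrades heme (3.95, SE 0.74), and Acod1 (4.04, SE 0.62) rose. The neutrophil granule genes Ngp (5.26, SE 0.95) and Mmp8 (4.3, SE 0.79), S100a8 (3.32, SE 0.62), Csf3 (3.55, SE 0.72), Nlrp3 (3.01, SE 0.5), Cxcl10 (3.42, SE 0.71) and the antiviral gene Oasl1 (3.16, SE 0.59) rose as well. Reg4 (-5.29, SE 0.76), Hoxd13 (-7.3, SE 0.96), Eno3 (-4.1, SE 0.68), AI854703 (-4.78) and Gjb5 (-4.25) fell. Ephb6 (a ratio of 46.2, counting interval 12.5 to 387), the Cphx homeobox genes (Cphx3 at least 55.1-fold) and Klk15 (at least 44-fold) were lower. Adjusted p of the genes with an SE lay between 0.00016 and 0.0324 (edgeR, Benjamini-Hochberg). Genes of pancreatic digestion filled the largest increases: Cel (ratio 11400, 2050 to 452000), Try5 (13.16), Try4 (13.12), Pnliprp1 (12.92), Cela2a (12.89), Pnlip (12.82), Amy2b (12.6), Ctrb1 (12.51) and Cpa1 (12.39). They rested on MCJ-deficient PP replicate 24, without which Try4, Pnliprp1, Pnlip and Amy2b had the other sign.

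Among lists, red blood cell markers (4 of 4 rose, median 7.13), neutrophil markers (12 of 12 positive, 7 rose, 3), the TNF pathway (7 of 28 rose, 1.78; Ier3 2.38), interferon-stimulated genes (37 of 38 positive, 5 rose, 1.33; Rsad2 3.11, Tap1 2.49) and the lysosome (3 of 29, 1.03; Ctsz 1.99) were higher. These and the other list calls of this comparison were lost with an estimated correlation (smallest adjusted p 0.105, camera). Classical activation (6 of 16, median 2.46), cytokines (6 of 24, 2.54), chemokines (4 of 28, 2.04), phagocytosis (4 of 26, 1.87; C5ar1 2.81), macrophage markers (14 of 14 positive, 1 rose, 1.51) and glycolysis and hypoxia (20 of 22 positive, 0 called, 0.69; Vegfa 1.58) followed. Adjusted over the list alone, 4 red blood cell, 9 neutrophil and 4 macrophage markers, 19 TNF pathway, 8 interferon-stimulated, 19 lysosomal, 13 classical activation, 11 phagocytosis and 10 glycolysis genes, 11 cytokines and 13 chemokines rose. Complex I (37 of 37 negative, 16 adjusted over the list alone, median -0.66; Ndufa9 -0.81), complexes II to V (38 of 38, -0.59), fatty acid oxidation (-0.39; Hadh fell by 1.05) and colonocyte markers (1 of 18 fell, 5 adjusted over the list alone, -0.55; Car1 fell by 1.42) were lower. Smooth muscle markers (median -1.91; Cnn1 -3.56) and cell cycle genes (26 of 30 negative, -0.54) were lower too. Camera passed 29 of 40 lists (adjusted p from 2.11e-12 to 0.0382). Of these, 20 passed whichever single library was left out. List calls ended for 4, 1 and 3 without MCJ-deficient NP replicates 19, 20 and 21 (highest adjusted p 0.0738, 0.0719 and 0.187, camera) and for 3, 6 and 3 without MCJ-deficient PP replicates 22, 23 and 24 (0.159, 0.112 and 0.125).

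MCJ-deficient mice had 228 genes higher and 66 lower with antibiotic (edgeR, Benjamini-Hochberg, 3 against 3, unadjusted p under 0.05 for 2417, 923 by DESeq2). The number was 37, 27 and 12 without MCJ-deficient NP replicates 19, 20 and 21 and 96, 87 and 634 without MCJ-deficient PP replicates 22, 23 and 24. Of 66 named genes 8 (Cphx1, Cphx2, Cphx3, Hoxd13, Reg4, Hba-a1, Hba-a2 and Hbb-bs) passed whichever single library was left out. Calls ended for 54, 52 and 58 without MCJ-deficient NP replicates 19, 20 and 21 (highest adjusted p 0.215, 0.152 and 0.24, edgeR, Benjamini-Hochberg). They ended for 26, 34 and 9 without MCJ-deficient PP replicates 22, 23 and 24 (0.176, 0.236 and 1). Without replicate 24 only 63 of the 66 could be tested, since Try5, Ctrb1 and Cpa1 fell below the filter on low counts. The genotypes shared 125 genes higher with antibiotic (7.9 by chance) and 24 lower ones (0.6 by chance). Fisher's exact test gave p = 3.02e-123 and 1.14e-32 (genes are not independent replicates).

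Of the lists not given so far, genes of oxidative stress and NADPH oxidase were higher with DSS in MCJ-deficient mice (4 of 25 rose, 6 adjusted over the list alone, median 0.16), led by the oxidase subunits Ncf1 (5.14), Ncf4 (5.51) and Cybb (4.75). Camera gave an adjusted p = 0.00835, and an adjusted p = 0.113 with an estimated correlation. Mast cell markers were higher with DSS in wild-type mice (1 of 7 rose, 2 adjusted over the list alone, median 6.81, 3.95 with genes at 0 at their bound), with the protease Mcpt2 at a ratio of 145 (counting interval 25.8 to 5760; adjusted p = 0.306 with an estimated correlation, camera). T and NK cell markers followed there (0 of 13 called, 2 adjusted over the list alone, median 0.76; Cd3d at least 33.6-fold higher; adjusted p = 0.345 with an estimated correlation, camera). B cell markers were higher with antibiotic in wild-type mice (1 of 7 rose, 1 adjusted over the list alone, median 3.41), with the receptor Cd22 at a ratio of 191 (52.4 to 1580; adjusted p = 0.185 with an estimated correlation, camera). The inflammasome list did not pass for MCJ loss in NP (0 of 17 called, median 0.33, adjusted p = 0.189, camera; Nlrp3 1.27, Nlrp6 -0.66). Nor did markers of crypt stem cells (1 of 7, Cd44, rose, median -0.14, adjusted p = 0.73, camera; Axin2 -0.99).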

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

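The tests of genes for a difference between conditions were planned; the contrast of the mitochondrial share, the permutation of the macrophage sum and the tests of explanations in this part were chosen only after the results were seen.

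A difference of the MCJ effect between NN and PP singled out 9 genes (edgeR quasi-likelihood test, Benjamini-Hochberg). Sis, a sucrase of enterocytes, shifted by -6.97 (adjusted p = 0.00554, edgeR, Benjamini-Hochberg). It had 1, 1 and 0 counts in wild-type NN against 55 and 77 in MCJ-deficient NN, and 367, 374 and 316 against 177, 236 and 103 in PP. Reg4, a lectin of secretory crypt cells, shifted by -6.94, from 2027, 801 and 1656 against 6488 and 5050 counts in NN to 1888, 1003 and 757 against 38, 41 and 7 in PP. Plet1, of epithelial progenitors, shifted by 3.59, from 451, 588 and 295 against 249 and 310 counts in NN to 1406, 2628 and 1687 against 12490, 7578 and 8783 in PP. The globins Hbb-b1 (6.49), Hba-a2 (6.28) and Hba-a1 (6.1) shifted up. Bicd1 (-9.38) had 0 counts in wild-type NN libraries against 73 and 125, Cenpq (-7.85) had 0, 0 and 1 against 110 and 66, and Npy1r (-17.92) had 0 in wild-type NN and in MCJ-deficient PP. The fitted differences of these genes near 0 counts depend on the prior count and are not bounds, and Npy1r was named after its values were seen.

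The share of mitochondrial transcripts was singled out because the MCJ effect in NP exceeded the mean effect of NN and PP by 20.7 percentage points (exact two-sided permutation within conditions, unadjusted p = 0.0065). The share was lower in MCJ-deficient mice of NN and PP. More macrophage RNA, if it lowered the share, would have lowered it in NP too, where macrophage markers differed most. The difference there was 4.5 points. Whether macrophage RNA lowers the share was not shown, and colonocyte sums differed little by genotype in NP (log2 ratio -0.08). Other parts of the mix differed where the gap lay (colonocytes -0.3 in NN, red blood cells 3.49 in PP), so the mix of cells stays open. Counts on gene numbers without a name did not carry the lower share, since leaving these out kept at least 97.5% of the gap. More nuclear RNA may lower the share and stays open: the smallest log2 fold change of the nuclear RNAs Malat1 and Neat1 in NN and PP was 0.22 (SE 0.23), while Neat1 in NN had 1.22 and both in PP had 1.35 and 0.87. A lower mitochondrial content of cells without MCJ, the biological explanation, was not tested and stays open, as do the state of the RNA and sex, although the 2 wild-type NN libraries with Xist counts (2048 and 1100) had shares of 38.86 and 42.17% against 23.12 and 28.35% in the MCJ-deficient ones, which also had them.

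Myeloid genes were higher in MCJ-deficient NP libraries. A lower share of epithelial RNA alone would have raised markers of all other cell types alike, yet the highest median among neutrophil (0.16), fibroblast (-0.64) and T and NK cell markers (-0.29) differed from that of macrophage markers (3.2) by -3.04. A rise in each macrophage alike in NP and PP has values against it: the genes higher in NP had a median of 0.38 in PP (-0.14 to 0.99 as single libraries were left out). It stays open because the MCJ effect on the macrophage sum differed between PP and NP by no more than the spread (-2.2; 46 of 400 arrangements, exact two-sided permutation, p = 0.115) and 0 of the 142 genes passed for that difference. A larger share of macrophage RNA, more entry of monocytes under DSS without MCJ, the biological explanation, and another yield of cells from the digestion were not tested apart.

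Red blood cell transcripts were higher in MCJ-deficient PP libraries. A single library did not carry the rise, because the median of the markers stayed at 3.77 or above without each MCJ-deficient library in turn (4.31, 3.77 and 4.98 without replicates 22, 23 and 24). Bleeding into the injured colon without MCJ, the biological explanation, and less washing of the tissue would both bring blood, and both stay open.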

How the results depend on the processing

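Alternatives chosen after the data were seen are named with the processing. The others were planned. Of alternatives tried on counts of genes, lists and overlaps, 182 kept the count within 1.5 times or the call, 44 gave more and 40 fewer. Many of the 182 compared 0 with 0, and a looser limit cannot lose calls. Neither shows robustness. Of those tried on named genes and lists, 5767 kept direction and call, 1317 lost the call, 89 gained it, 1 moved and 6 reversed. For each change below without a stated reason the cause was not tested.

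With an adjusted p under 0.01, by construction a stricter limit, the called genes numbered 30 for MCJ in NP, 129 for DSS in wild-type and 186 in MCJ-deficient mice, 249 and 22 for antibiotic, and 1 for the MCJ effect in PP against NN; lists for MCJ in PP numbered 10. Under 0.1 they numbered 220 in NP, 697 for DSS in wild-type, 1191 and 659 for antibiotic in wild-type and MCJ-deficient mice, 1 for NP against NN and 10 for PP against NP. With no filter on low counts edgeR called 9 genes in NN, 353 in NP, 1 in PP, 558 for antibiotic in MCJ-deficient mice, 16 for NP against NN, 36 for PP against NP and 38 for PP against NN. A mean count of at least 10 gave 1 for PP against NP, and of at least 50 gave 1 for NP against NN and 2 for PP against NP.

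DESeq2 called 312 genes in NN, 361 in NP, 88 in PP, 1092 and 787 for DSS in wild-type and MCJ-deficient mice, 1380 and 923 for antibiotic, and 141, 81 and 162 for the differences NP against NN, PP against NP and PP against NN. The corresponding edgeR counts were 0, 145, 0, 414, 352, 748, 294, 0, 0 and 9. One fit of all 17 libraries gave 3 genes in NN, 1 in NP and 8 in PP. Robust estimation gave 104 for antibiotic in MCJ-deficient mice and 2 for PP against NN.

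With an estimated correlation camera passed 0 lists for MCJ in NN, NP and PP, 0 and 12 for DSS in wild-type and MCJ-deficient mice, and 0 and 0 for antibiotic. A preset correlation of 0.05 gave 8 lists for MCJ in PP, and ranking by log2 fold change gave 15 for antibiotic in MCJ-deficient mice. Fry, which asks whether a list moves one way on balance, passed 0 lists for MCJ in NN, NP and PP, 18 and 22 for DSS and 17 and 17 for antibiotic.

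Leaving out single libraries gave 0 to 1 genes in NN, 20 to 203 in NP, 0 to 6 in PP, 267 to 769 for DSS in wild-type and 45 to 340 in MCJ-deficient mice, 215 to 1313 and 12 to 634 for antibiotic, and 0 to 41, 0 to 29 and 1 to 78 for the differences NP against NN, PP against NP and PP against NN. Lists ran from 8 to 14 in NN, 14 to 20 in NP, 10 to 20 in PP, 19 to 26 and 30 to 32 for DSS, and 20 to 23 and 23 to 29 for antibiotic. Where MCJ-deficient NN kept 1 library, that library was assumed to vary like the other groups. Without MCJ-deficient PP replicate 24 Try4 (adjusted p = 0.968), Pnliprp1 (0.876), Pnlip (1) and Amy2b (0.888) reversed for antibiotic (edgeR quasi-likelihood test, Benjamini-Hochberg), and over the libraries left out their lowest adjusted p were 0.0237, 0.0208, 0.0237 and 0.0208. Interferon-stimulated genes reversed in PP without MCJ-deficient replicate 23 (adjusted p = 0.776, camera; 0.000245 to 0.965 over the libraries left out) and classical activation without wild-type replicate 11 (0.914; lowest 0.000126). The log2 fold change of Dnajc15 with DSS in wild-type mice moved from 0.04 to -0.28 without wild-type NN replicate 2, which had 359 counts of it (adjusted p = 0.886, edgeR quasi-likelihood test, Benjamini-Hochberg).

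The titles of NN give mouse numbers 1 and 2 to both genotypes. With these as a block edgeR called 0 genes in NN, and the paired libraries' deviations correlated at -0.06 and -0.05, so the numbers did not mark shared variation there. Titles outside NN repeat some numbers as well, between genotypes in PP and between MCJ-deficient NN and NP. Those were not checked. Alternatives planned for authors' tables or normalized values (Benjamini-Hochberg recomputed, Bonferroni, another pseudocount, enlarged standard errors, centring) did not apply to raw counts and were not run. Depth limited genes at 0 counts to bounds, and the simulated recovery of 2-fold changes (14% in NP, 1% in PP) shows that small changes were mostly below what these numbers of libraries can call.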

Other observations

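The tests of explanations and the splits of libraries in this part were chosen only after the results were seen. Averaged over conditions, genes other than Dnajc15 came close to passing without reaching it, each with an adjusted p = 0.0532 (edgeR quasi-likelihood test, Benjamini-Hochberg). Among them were Insig1, which holds back sterol synthesis (1.03, SE 0.16), the kinase Mapk6 (0.94, SE 0.17), the vesicle fusion ATPase Nsf (1.03, SE 0.19), Tnfrsf9, a costimulatory receptor (3.37, SE 0.62), and Serpinb2, a protease inhibitor of macrophages (2.74, SE 0.52). Lower were the chaperone Hsph1 (-1.53, SE 0.28), Ly6c1 (-1.08, SE 0.21) and Mettl17, needed for mitochondrial ribosomes (-1.16, SE 0.21). These genes were named after their values were seen.

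A repeated region of chromosome 14 (25888403 to 26235744) held several of the lowest values by genotype: Plac9a (-1.82, SE 0.33), Plac9b (-1.76, SE 0.32), Gm9780 (-1.78, SE 0.32) and Cphx1, Cphx2 and Cphx3 (-3.44, -3.44 and -3.42). Counts of such near-identical copies are uncertain one by one. Dnajc15 (77826217 to 77874917) lies on the same chromosome, as did 9 of the 25 genes with the smallest p, among them Fbxo34 (47472533 to 47531962; 0.83, SE 0.16) and Mettl17 (51884842 to 51891868) between the region and Dnajc15. A stretch of chromosome 14 from another strain was tested as a source: outside Dnajc15 and this region 4.91% of 550 genes of chromosome 14 had an unadjusted p under 0.01 against 4.62% of 15829 others (Fisher's exact test, two-sided, p = 0.756). A short stretch beside Dnajc15 would not hold the region, and whether a long one reached it stays open.

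The level of Ang4, an antimicrobial ribonuclease, was 142 ± 17.7 CPM in wild-type NN, 4.92 ± 2.19 in wild-type NP and 153 ± 85.4 in wild-type PP, and 13 ± 7.46, 35 ± 30.8 and 21.9 ± 3.42 in MCJ-deficient mice (mean ± SD).

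Pancreatic digestion genes stood out in MCJ-deficient PP replicate 24. Carry-over of exocrine pancreas may be the source: 9 other acinar genes (among them Prss2, Cpb1 and Clps) were higher there than in the highest other library by a median ratio of 176 (3.46 to 4350).

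Hoxd13 and Hoxb13, of the hindmost gut, were lower with antibiotic. Another stretch of the bowel in these preparations may be the reason: the other posterior homeobox genes measured had a median of -2.38 in wild-type and -1.65 in MCJ-deficient mice, with several near 0 counts. Hoxd13 also had lower values in MCJ-deficient mice, at -1.74 (SE 0.44) in NP and -5.41 (SE 1.6; 2, 2 and 0 counts) in PP, and averaged -2.4 over conditions (adjusted p = 0.123, 0.938 and 0.0532, edgeR quasi-likelihood test, Benjamini-Hochberg), while Hoxb13 had -0.435 and 0.64. Whether the stretch of bowel differed between genotypes, and whether antibiotic changed the epithelium, was not tested.

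Sex-linked transcripts differed within groups and, in MCJ-deficient mice, between NN and NP. Xist had 3822 counts in MCJ-deficient NP replicate 21 against 4 and 0 in replicates 19 and 20, although that library also had 518 counts of the Y-linked Ddx3y, so that whether it came from 1 mouse stays open.

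Splits of the same libraries into other groups of 3 were counted, and each count of splits or assignments below includes the real one. For MCJ in NP 1 of 10 splits gave as many genes as the real one (145, highest other 0) and 4 of 10 as many lists (14, highest other 16). For MCJ in PP 7 of 10 gave as many lists (16, highest other 24). For DSS in wild-type mice 1 of 10 gave as many genes (414, highest other 1) and 1 as many lists (26, highest other 13). With antibiotic 1 of 10 gave as many genes in wild-type (748, highest other 0) and 1 in MCJ-deficient mice (294, highest other 0), and 4 and 1 as many lists (23, highest other 27; 29, highest other 23). In all of these 10 splits are too few for a share under 0.05. For the MCJ effect in PP against NP, 15 of 40 assignments drawn from 200 gave as many lists (15, highest other 25), so chance is not excluded for these. Where the real count of genes was 0 a count of splits tests nothing and is not given. In 1 assignment of PP against NP 74 genes were called, and the reason was not tested.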
